A study of Mus musculus with 4 samples.

How the data were processed

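Gene expression was measured in type II alveolar epithelial cells (AEC2), the surfactant-producing cells of the lung alveolus, sorted by flow cytometry from mouse lungs. The 4 arrays covered wild-type and Tlr4-/- mice, untreated or 4 days after bleomycin, a drug that injures the lung epithelium. Per the labels' protocols, each RNA sample came from cells pooled from 4 to 5 mice, and the cDNA was amplified and biotin labelled with commercial kits before hybridisation to an Affymetrix 3' expression array. Each group therefore had 1 array, and no spread between replicates of a group could be measured.

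The deposited values were read as log2 signals per probe set, from their range and from the nearly equal quantiles of the columns. The array medians lay between 6.93 and 6.98. The software and the between-array normalization used by the authors were not given in the sources used here, nor were detection calls, so the log base rests on the values alone. Of 45101 probe sets, 64 were array controls, 34958 carried 1 gene symbol in the platform annotation, 932 carried several and 9211 had none. For 34754 of the probe sets with 1 symbol the Entrez identifier was found in the RefSeq gene table, and for 204 the annotation's own name was kept. Probe sets with several symbols or none were left out of the gene-level results.

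Probe sets were averaged per gene, giving 18194 genes, 9012 of them with several probe sets. Genes whose mean over the 4 arrays exceeded the median of all genes, a log2 signal of 7.05, were kept, which left 9097. The 4 pairwise differences and the difference between the bleomycin responses of the genotypes were computed as log2 values with a threshold of 2-fold and no test. The bleomycin effect across both genotypes and the genotype effect across both treatments were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust off), in an additive model with both factors and 1 residual degree of freedom per gene. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. This model treats a difference between the genotypes' responses as error. The prior had 11.4 degrees of freedom and gave a standard deviation of 0.23 (log2) for a difference between 2 arrays. This served as the spread between arrays for values without a test. It and the limma standard errors rest on differences between the genotypes' responses, not on replicate arrays or pools.

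For the gene lists fixed beforehand, the median difference over the members past the filter was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 brightness bins. With 31 lists, 1.55 per comparison would fall outside the central 95% by chance if lists and arrays were independent. Counts of list members below, also where called measured, cover only members past the filter. Dimmer members on the array were left out of them. The lists covered AEC2, AEC1 and transitional epithelial markers, S phase, G2/M, p53 targets, hyaluronan handling, Toll-like receptor components, NF-kB targets, the IL-6 and STAT3 axis, interferon-stimulated genes, MHC class II, sterol and fatty acid synthesis, the unfolded protein response, NRF2 targets, Wnt and FGF signalling, TGF-beta targets and matrix, apoptosis regulators, oxidative phosphorylation, ribosomal proteins, and immediate early genes. Marker lists of other cells covered leukocytes and macrophages, neutrophils, lymphocytes, endothelium, fibroblasts, club, ciliated and basal airway cells, mesothelium, and erythroid cells with platelets.

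Genes were named by a rule fixed before the data were examined. Tlr4 came first. For the bleomycin effect, the 12 highest and 12 lowest genes by the smaller of the genotypes' absolute differences were taken, with the same direction in both. For the genotype effect, 10 each way were taken by the smaller of the treatments' differences, and for the difference in response, 10 each way by its size. Up to 4 members of each list were added per comparison, by size. Predicted or clone-like genes, receptor and immunoglobulin segments, Y-linked genes and Xist were passed over. Of the 64 entries in the bleomycin, genotype and response groups, 13 had several probe sets above the floor, and 0 had one that went the other way. Further members of the lists, and genes of the circadian clock, are given as examples chosen after their values were seen.

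The limma step was tested on 20 simulated data sets of 9097 genes for the bleomycin effect. Noise was drawn independently for each gene and array, with no shift shared by the genes of a pool. No difference between the genotypes' responses was put in either, so the figures may not carry over to the real pools. A median of 98.5% of genes changed 2-fold and 100% of genes changed 4-fold were recovered. Unchanged genes made up a median of 12.2% of the calls at an adjusted p under 0.05 (range 1.07% to 20.0%) and 3.67% under 0.01. At the median, the simulated calls thus held more false ones than their threshold states, and the real calls may do so too.

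Results were also computed with quantile normalization, cyclic loess, centring on array medians, no filter, a filter at the 75th percentile, the probe set with the highest mean, a 3-fold threshold, eBayes with trend and robust on, a fit with no other factor, and leaving out each array. Pseudocounts were not tried because the values were already on a log scale. A p threshold of 0.01 and centring of each difference on its own median were added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.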

Results

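AEC2 were profiled on 4 arrays, 1 each for wild-type untreated, Tlr4-/- untreated, wild-type day 4 and Tlr4-/- day 4 after bleomycin. The series asks how hyaluronan and TLR4, a receptor of innate immunity, bear on the renewal of these alveolar stem cells and on lung fibrosis. The AEC2 genes Sftpc, Sftpb and Lyz2 were among the strongest signals on every array. Over all probe sets the arrays correlated with a Pearson's r of 0.973 to 0.992 across probe sets, which are not independent replicates. The closest pair was the wild-type and Tlr4-/- day 4 arrays (r = 0.992), and the 2 untreated arrays correlated at 0.982. The Tlr4-/- untreated array correlated with the wild-type day 4 array at 0.983. Differences below are log2 values, and those between single arrays have no replicate check. Without detection calls, a fold over a dim untreated signal, as for Timp1 (5.56 in wild type), Clec4n (5.87) or Usp18 (6.44), has an uncertain size.

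Tlr4 itself was read by 4 probe sets. The only probe set that was lower in both Tlr4-/- arrays by more than the spread between arrays was 3.09-fold lower in the Tlr4-/- untreated array than in wild type and 6.42-fold lower at day 4. Another 2 were higher in the Tlr4-/- arrays, by 0.66 and 0.43 when untreated and by 0.41 and 0.49 at day 4. The last was dim on every array, between 3.89 and 4.05. The allele and the place of each probe set relative to the deleted part were not given in the sources used here, so probe sets outside that part check nothing. The first of these probe sets was higher by 0.21 after bleomycin in wild type.

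After bleomycin, genes of macrophages, interferon response, p53 response and epithelial injury were higher in the wild-type pool of sorted AEC2. Fewer genes were lower than higher. Of 9097 genes, 232 were at least 2-fold higher and 28 at least 2-fold lower, with 47 lower after quantile normalization and 190 higher and 43 lower once the difference was centred on its own median. Phlda3, a p53 target that restrains Akt, was higher by 3.25, and Timp1, an inhibitor of metalloproteinases, by 3.34. The interferon-inducible gene Ifi27l2a was 12.8-fold higher, the complement gene C1qb 6.47-fold and the tight junction gene Cldn4 5.86-fold. Among lower genes, the paraoxonase gene Pon1 was 3.62-fold and Gpr153 2.58-fold lower. The highest list medians were 1.31 for leukocyte and macrophage markers, 0.98 for mesothelial markers, 0.91 for interferon-stimulated genes, 0.76 for p53 targets and 0.68 for transitional epithelial markers, all above the central 95% of random lists. Ciliated airway, club, immediate early, Wnt and FGF, and AEC2 lists lay below it, with medians of -0.42, -0.20, -0.14, -0.07 and -0.06.

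In the Tlr4-/- pool of sorted AEC2, mesothelial and leukocyte lists had the highest medians. Of the 9097 genes, 223 were at least 2-fold higher after bleomycin and 81 at least 2-fold lower. The complement gene C1qb was 6.83-fold and Ifi27l2a 6.56-fold higher, and the ubiquitin-like protease gene Usp18 went from a dim 5.52 to 8.87, while the small GTPase gene Gem was 5.48-fold and Pon1 4.28-fold lower. The medians were 1.86 for mesothelial markers, 1.64 for leukocyte and macrophage markers, 0.81 for interferon-stimulated genes, 0.84 for p53 targets and 0.85 for transitional markers. Wnt, FGF and progenitor signalling had a median of -0.27, with Fgfr2, a growth factor receptor of AEC2, lower by -0.80 and Notum by -0.66. The AEC2, sterol and immediate early lists had medians of -0.23, -0.21 and -0.15, and these 4 lists lay below the central 95% of random lists. The count of lower genes was 127 with the probe set of highest mean in place of the average.

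**Figure D1:**
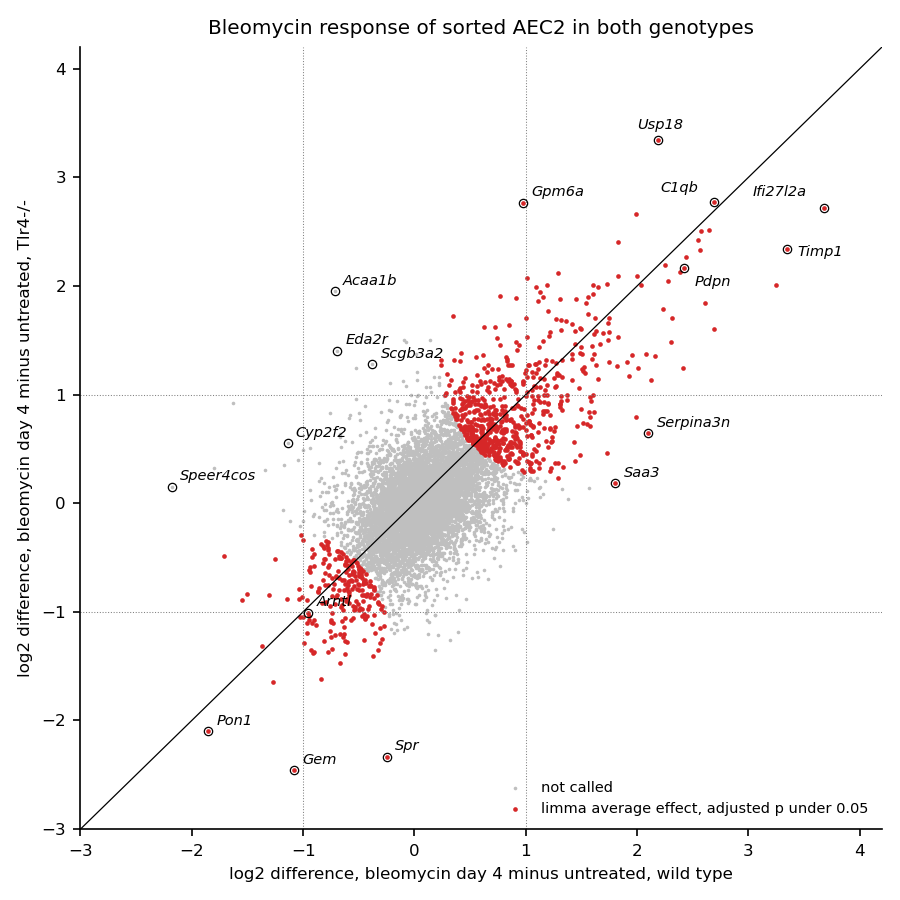
Log2 difference between bleomycin day 4 and untreated in wild type (horizontal) and Tlr4-/- (vertical) for 9097 genes, with the limma calls of the average effect in red, the line of equality and dotted lines at 2-fold. C1qb, Pdpn and Pon1 lie near the line of equality, whereas Acaa1b and Spr lie far from it.

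The responses of the genotypes went together across genes (Pearson's r = 0.605, Spearman's rho = 0.505, descriptive only). Both genotypes shared 125 genes at least 2-fold higher, against 5.69 for independent lists, and 6 at least 2-fold lower, against 0.249. No gene was 2-fold higher in one genotype and 2-fold lower in the other (0 genes). The 2 differences shared no array, but both may hold a difference in sex, since Y-linked genes were higher after bleomycin in both genotypes.

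Across both genotypes, limma called 653 genes that rose and 230 that fell after bleomycin. Ifi27l2a rose by 3.19 ± 0.21 (SE, limma average over 2 pairs of arrays, higher in 2 of 2 genotypes, adjusted p = 2.61e-06), C1qb by 2.73 ± 0.16, Clec4n, a C-type lectin receptor of myeloid cells, by 2.58 ± 0.16, and S100a4 by 2.54 ± 0.16. Cldn4 rose by 2.49 ± 0.16, Timp1 by 2.84 ± 0.21, Usp18 by 2.77 ± 0.23 and the AEC1 gene Pdpn by 2.30 ± 0.16. Dglucy, C1qa, Aaas and Ifit1 completed the 12 highest, with averages of 2.35, 2.22, 2.26 and 2.16. Pon1 fell by 1.98 ± 0.16 and Gem by 1.77 ± 0.25, followed by Ccl27a, Gpr153, Tox3, Aox3, Rnf186, Npas2, Grb7, Anpep, Fam71a and Arntl, with averages from -1.46 to -0.98. Gem was not called by limma without the filter, nor Arntl with the probe set of highest mean. Arntl and Npas2 encode transcription factors of the circadian clock. The hours at which lungs were taken were not given in the sources used here. The Y-linked gene Eif2s3y was higher after bleomycin by 2.04 in wild type and 2.01 in Tlr4-/-, and Xist differed by -0.62 and -1.27; no call was adjusted for the sex of the mice, which was not given either.

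Among p53 targets, 16 of 23 measured members rose and 0 fell, and the count adjusted over the list alone was also 16. Phlda3 rose by 2.63 ± 0.23, Ccng1 by 2.15 ± 0.22, Ddit4l by 2.01 ± 0.17 and Cdkn1a, the cell cycle inhibitor p21, by 1.55 ± 0.19. Interferon-stimulated genes rose in 16 of 18 (17 adjusted over the list alone), with Oasl2 at 1.66 ± 0.18, Zbp1 at 1.60 ± 0.18 and the chemokine Cxcl10 at 1.30 ± 0.18. Transitional epithelial markers rose in 11 of 18 (12 higher and 1 lower adjusted over the list alone), led after Cldn4 by Sprr1a at 1.63 ± 0.21, the galectin Lgals3 at 1.52 ± 0.17 and the keratin Krt7 at 1.49 ± 0.17. Krt8, a keratin often used for this state, was higher by 0.33 and did not pass. AEC1 markers rose in 4 of 17 (4 adjusted over the list alone), namely Pdpn, Akap5, Cav1 and Hopx, while Ager and Aqp5 were higher by 0.11 and 0.34 without passing.

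AEC2 markers had 3 of 21 members that fell and 0 that rose (3 and 0 adjusted over the list alone). These were Acoxl by 0.93 ± 0.18, Lgi3 by 0.69 ± 0.16 and Hc by 0.59 ± 0.16. The surfactant gene Sftpc differed by 0.03, at signals close to the top of the range where an array responds least. Immediate early and dissociation genes fell in 4 of 26 and rose in 1 (5 and 3 adjusted over the list alone). Klf2 and Egr1 fell by 0.85 ± 0.16 each, and the heat shock gene Hspa1b rose by 0.63 ± 0.18.

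Markers of other cells moved beside these groups. Leukocyte and macrophage markers rose in 12 of 15 (14 adjusted over the list alone), with C1qc at 2.32 ± 0.18, Itgax at 2.12 ± 0.17 and Mrc1 at 1.67 ± 0.17. The pan-leukocyte gene Ptprc was higher by 0.53 ± 0.18 and did not pass (limma adjusted p = 0.0901). Mesothelial markers rose in 3 of 3 (3 adjusted over the list alone), Gpm6a by 1.87 ± 0.30, Msln by 1.48 ± 0.19 and Upk3b by 1.12 ± 0.21. Of fibroblast markers 1 of 5 rose (2 adjusted over the list alone), which was Col1a1 at 1.52 ± 0.16. The neutrophil gene Ltf and the lymphocyte gene Cd2 rose, 1 of 3 and 1 of 2 members past the filter. The counts adjusted over the list alone were the same. The array held 10 neutrophil and 14 lymphocyte members. Ciliated airway markers fell in 2 of 7, Dynlrb2 and Tppp3 (2 adjusted over the list alone). No member past the filter of the club (0 of 11), basal (0 of 3), endothelial (0 of 2) or erythroid and platelet (0 of 4) lists was called. Pf4 was 1 call adjusted over the list alone. Only 2 of the 15 endothelial members on the array passed the filter, so that list says little about endothelial cells.

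Inflammatory lists rose in part. Leukocyte and macrophage markers rose too, so RNA of AEC2 and of other cells cannot be told apart for the calls of these and the other lists. NF-kB targets rose in 7 of 22 (8 adjusted over the list alone), including the cytokine genes Lif at 1.43 ± 0.16 and Il1b at 1.24 ± 0.16 and the chemokine genes Ccl7 at 1.06 ± 0.16 and Ccl2 at 0.92 ± 0.16. Toll-like receptor components rose in 4 of 10 (4 higher and 1 lower adjusted over the list alone), namely Tlr2 at 1.18 ± 0.16, Cd14, Irak2 and Irak1. The IL-6 and STAT3 axis rose in 5 of 19, with Serpina3n at 1.37 ± 0.26 and Reg3g at 1.27 ± 0.17, and fell in 1, the fibrinogen gene Fgg (5 and 1 adjusted over the list alone). Of MHC class II genes 1 of 7 rose, the protease Ctss at 1.89 ± 0.19 (2 adjusted over the list alone).

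In the hyaluronan list, 1 of 8 measured members rose and 2 fell (1 and 2 adjusted over the list alone). The scavenger receptor Stab1 rose by 0.68 ± 0.17, and Itih1 and Itih4, members of the family whose heavy chains bind hyaluronan, fell by 0.72 ± 0.16 and 0.70 ± 0.17. The receptor Cd44 was higher by 0.25 ± 0.16 without passing. The hyaluronan synthase gene Has2 was below the filter at 4.99 to 5.16 on the 4 arrays, and Has3 was below it at 4.58 to 5.16. The synthase gene Has1 passed it at 7.91 to 8.15 and was higher after bleomycin by 0.11 in wild type and 0.19 in Tlr4-/-. These genes are given here although the rule did not name them.

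Metabolic, matrix, stress and cell cycle lists also held calls. NRF2 and oxidative stress genes rose in 5 of 19 (8 adjusted over the list alone), led by Akr1b8 at 1.57 ± 0.16 and Srxn1 at 1.11 ± 0.16. Oxidative phosphorylation rose in 6 of 25 (9 adjusted over the list alone), with Sdhb at 0.86 ± 0.16. TGF-beta targets and matrix rose in 5 of 17 and fell in 1 (6 and 1 adjusted over the list alone), with Vim at 1.73 ± 0.16, Tgfbi at 1.18 ± 0.19 and Ccn2 at 1.16 ± 0.17, and Lama3 fell by 0.59 ± 0.16. The stress response list rose in 3 of 26 and fell in 2 (3 and 2 adjusted over the list alone): the amino acid synthesis genes Psat1 and Asns and the p53 target Sesn2 rose, and the chaperone-pathway genes Pdia6 and Herpud1 fell. Apoptosis regulators rose in 4 of 18, among them Birc2, Apaf1 and Bak1, and Bik fell by 1.17 ± 0.18 (5 and 2 adjusted over the list alone). In G2/M, Ube2c rose by 1.24 ± 0.16 and Cdca8 by 0.98 ± 0.16, 2 of 7 members past the filter (6 adjusted over the list alone). The array held 27 members of G2/M, and the rest were too dim for the filter. In S phase 1 of 13 members past the filter rose, Mcm4 at 0.74 ± 0.19 (1 adjusted over the list alone), with 23 on the array. No member of the sterol and fatty acid (0 of 27), Wnt and FGF (0 of 24) or ribosomal protein (0 of 18) lists was called, with 0 adjusted over the list alone. Over all genes, 2176 had an unadjusted limma p under 0.05 against 454.9 by chance. Without the Tlr4-/- day 4 array 0 genes were called, and without the wild-type day 4 array 18 rose and 3 fell, in fits with no other factor; centring on array medians gave 378 and 106.

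**Figure D2:**
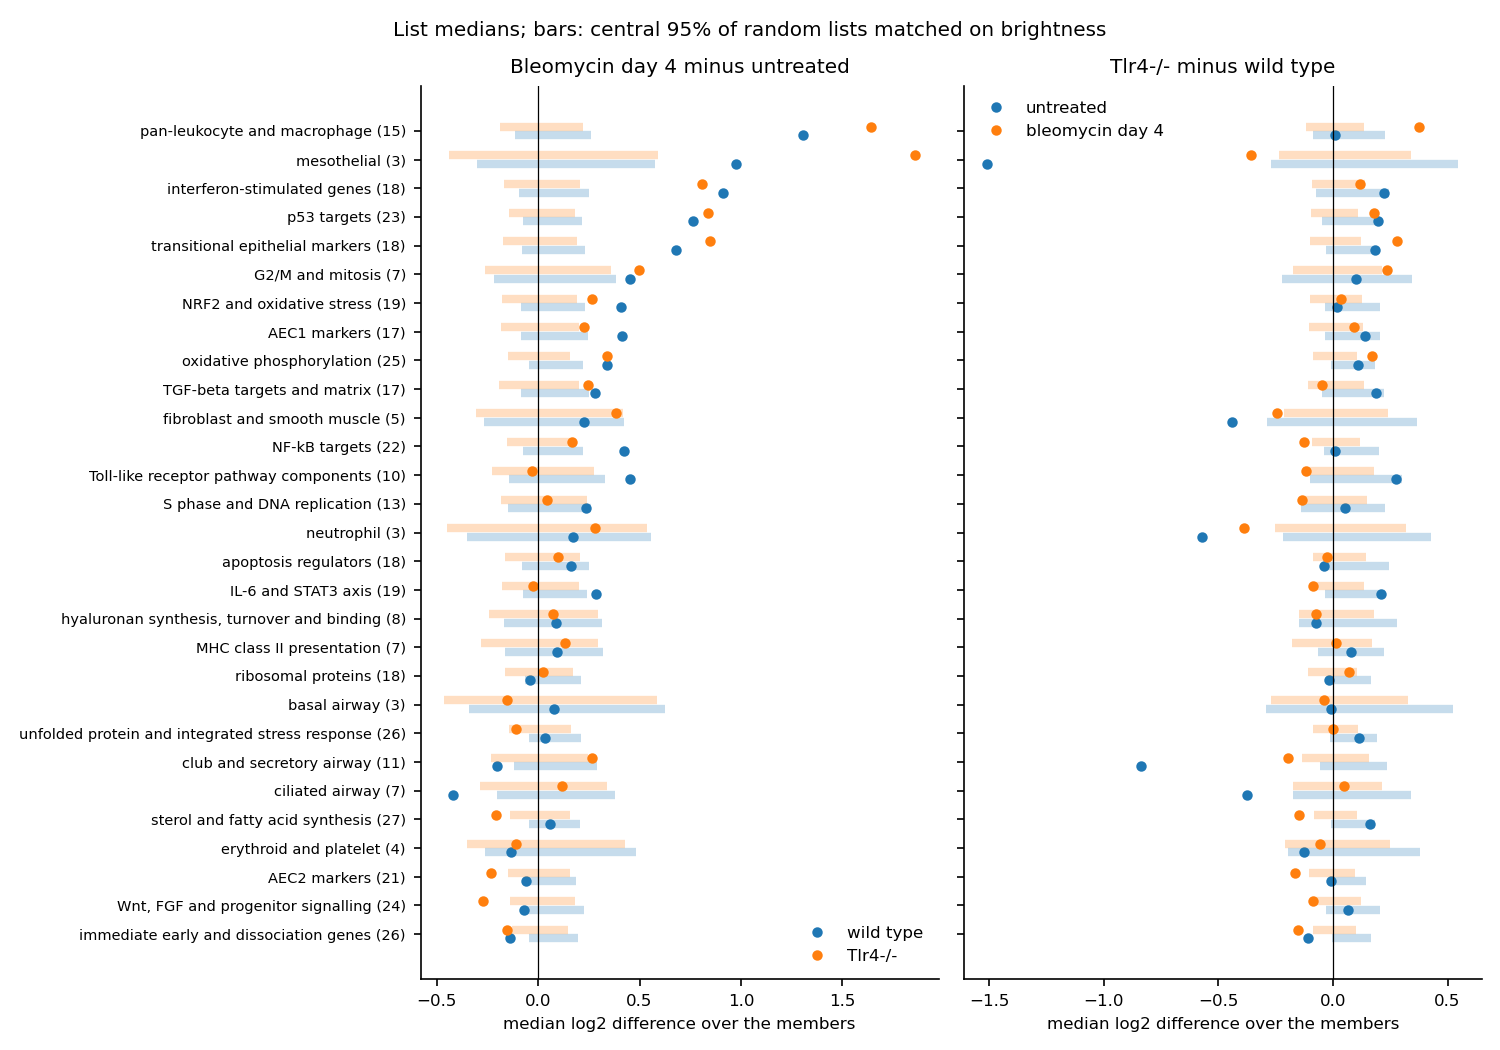
Median log2 difference of each fixed list with at least 3 measured members (number in brackets), for bleomycin against untreated in both genotypes (left) and Tlr4-/- against wild type in both treatments (right), with the central 95% of random lists as bars. Leukocyte and macrophage markers reach 1.31 and 1.64 after bleomycin, and mesothelial markers lie at -1.51 in the untreated genotype comparison.

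In the untreated pools of sorted cells, airway and mesothelial genes were lower in Tlr4-/- than in wild type. The acute phase gene Saa3 and part of the p53 targets were higher in Tlr4-/-. Airway and mesothelial genes mark cells other than AEC2. With 1 pool per group, a difference in the cells of the pools and an effect of genotype cannot be told apart. Of 9097 genes, 71 were at least 2-fold higher and 31 at least 2-fold lower, or 43 and 39 once the difference was centred on its own median. The mesothelial gene Gpm6a was lower by -2.15 and the airway secretory genes Bpifa1, Scgb3a1, Aldh1a1, Cyp2f2 and Scgb3a2 by -1.83, -1.65, -1.58, -1.54 and -1.49. The club, ciliated, mesothelial, fibroblast and neutrophil lists had medians of -0.84, -0.37, -1.51, -0.44 and -0.57, and immediate early genes of -0.11, all below the central 95% of random lists. Saa3 was higher by 1.68, the IkB-related gene Bcl3 by 1.40, Phlda3 by 1.42, Sprr1a by 1.52 and Ccng1 by 1.07. Of the p53 targets 15 of 23 were above 0 (median 0.20), with Eda2r lower by -1.37, and the IL-6 and STAT3 median of 0.21 lay within the central 95%. AEC2 markers had a median of -0.01 (0.04 after centring on array medians). With the probe set of highest mean the count of higher genes was 122.

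At day 4 the genotypes were closer, with 4 genes at least 2-fold higher (11 with the probe set of highest mean) and 5 at least 2-fold lower in Tlr4-/-. The lower genes were Spr (-1.73), which makes the cofactor tetrahydrobiopterin, Max (-1.23), Dbp (-1.13), Gem (-1.13) and the neutrophil chemokine Cxcl1 (-1.02). The higher genes with established names were Acaa1b (1.30) and Chtf8 (1.03), and the other 2 were predicted genes; Max, Dbp and Chtf8 were named after their values were seen. Medians of 10 lists lay below the central 95% of random lists: neutrophil (-0.39), mesothelial (-0.36), fibroblast (-0.25), club (-0.20), AEC2 (-0.17), immediate early (-0.15), sterol and fatty acid (-0.15), S phase (-0.14), NF-kB (-0.13) and Wnt and FGF (-0.09, but 0.08 with the probe set of highest mean). Among their members, Ccl5 was higher by 0.95, whereas Tnfaip3 and Nfkbia, inhibitors of NF-kB, were lower by -0.66 each, Cxcl2 by -0.67, the lipid regulator Srebf1 by -0.43 and the AEC2 transcription factor Etv5 by -0.54. Mvd and Dhcr7 of the sterol list were higher by 0.31 each. Leukocyte, transitional, G2/M, p53 and oxidative phosphorylation lists had medians of 0.38, 0.28, 0.24, 0.18 and 0.17, above the central 95%, with Itgax higher by 0.57 and Tnfrsf12a by 0.68.

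Across both treatments limma called 0 genes for genotype, with 822 genes at an unadjusted p under 0.05 against 454.9 by chance and a smallest adjusted p of 0.153. The zinc finger gene Rbak was higher in Tlr4-/- by 1.12 untreated and 0.87 at day 4, the carbonic anhydrase gene Car4 by 0.84 and 0.80, and Clec4n by 0.90 and 0.77. Ppp1r3b, Lactb, Atf5, Lsm2, Exosc9, Vps25 and Klhl13 were the other 7 highest, each higher by at least 0.67 in both. The airway gene Bpifb1 was lower by -0.84 and -0.93, Igfbp5 by -1.41 and -0.66, the calgranulin gene S100a9 by -0.61 and -0.80 and the mesothelial gene Upk3b by -1.51 and -0.52. Scaf1, Clec4d, Rara, Zfp946, Ccrl2 and Hoga1 completed the lowest 10. Adjusted over the list alone, 4 club, 3 mesothelial and 2 neutrophil markers were lower, and 4 transitional, 3 p53 and 3 interferon genes were higher, as was 1 gene each of the AEC1, G2/M, IL-6 and leukocyte lists. The genotype differences of the 2 treatments correlated weakly across genes (r = 0.134, rho = 0.143). No gene was at 2-fold in the same direction in both (0 higher, 0 lower, 2 opposite). Independent lists would share 0.0312 higher and 0.0170 lower genes, since few genes were at 2-fold at day 4. These counts of 0 therefore decide nothing. Tlr4 itself, averaged over its probe sets, was neither called nor at 2-fold in both treatments. Its lower probe set alone was 3.09-fold lower untreated and 6.42-fold lower at day 4. The lack of calls therefore does not show that no gene differed consistently by genotype. With a filter at the 75th percentile, 14 genes were called higher and 4 lower. In the 20 simulated data sets of 9097 genes, between 0 and 13 unchanged genes were called for genotype (median 0). These sets were not run with the filter at the 75th percentile, so they give no false-call range for the 14 and 4 calls.

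The bleomycin response itself differed between the genotypes for airway genes and for Saa3, Serpina3n and Spr among others, as values without a test. For Cyp2f2, Scgb3a2, Aldh1a1 and Gpm6a most of this difference lay between the untreated arrays. Tlr4-/- minus wild type was -1.54, -1.49, -1.58 and -2.15 when untreated. At day 4 it was 0.15, 0.17, 0.18 and -0.36. The signed difference, Tlr4-/- minus wild type, was 1 or more for 61 genes and -1 or less for 77, or 82 and 59 once each difference was centred on its median. Acaa1b, a peroxisomal thiolase gene, differed by -0.72 in wild type and 1.95 in Tlr4-/-, and the p53 target Eda2r by -0.69 and 1.40. Gpm6a, Aldh1a1, Cyp2f2, Scgb3a2, Speer4cos, Gatd3a, Pglyrp1 and Tmem198b made up the rest of the 10 highest, with response differences from 1.59 to 2.33. Spr had the lowest value at -2.09 (-0.25 in wild type and -2.33 in Tlr4-/-), and Saa3 was higher after bleomycin by 1.81 in wild type and 0.18 in Tlr4-/-. For Serpina3n, an acute phase protease inhibitor, these were 2.10 and 0.65, while the acute phase gene Hp had a response difference of 0.04 and Orm1, below the filter and dim when untreated (4.68 and 4.65), read 8.24 and 8.47 at day 4. Slc25a47, Lrrc51, Ppp6r1, Akr1c19, Ddx56, Cmas and Dnajb14 made up the rest of the 10 lowest, from -1.58 to -1.39. With the probe set of highest mean, 138 genes had a response difference of -1 or less.

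Several lists differed in the response. NF-kB targets had medians of 0.42 in wild type and 0.17 in Tlr4-/- (-0.02 with the probe set of highest mean), and Cxcl1 differed by 0.79 and -0.21, Tnfaip3 by 0.54 and -0.30. The chemokine gene Ccl5 of the same list ran the other way, at -0.22 and 0.95. The IL-6 and STAT3 axis had 0.29 and -0.03, with Bcl3 at 0.55 and -0.42 and Cebpd at 0.66 and -0.26. Il6 was below the filter; its values were 5.79 and 7.84 in wild type and 5.53 and 6.90 in Tlr4-/-, untreated and day 4. Toll-like receptor components had 0.45 and -0.03 (0.16 in Tlr4-/- with the probe set of highest mean), with Myd88 at 0.59 and 0.02, and Tlr4 itself belongs to that list. Sterol and fatty acid synthesis had 0.06 and -0.21. The medians of the response difference for these 4 lists were -0.24, -0.32, -0.33 and -0.26, below the central 95% of random lists. Their medians for Tlr4-/- minus wild type were 0.01, 0.21, 0.27 and 0.16 untreated, and -0.13, -0.09, -0.12 and -0.15 at day 4. For the IL-6 and Toll-like receptor lists both values lay within the central 95%. In S phase, the helicase gene Mcm2 was higher by 0.99 in wild type and differed by -0.26 in Tlr4-/-, and Mcm4 was higher by 1.11 and 0.37, while the median of the list's response difference, -0.11, lay within the central 95%. Mesothelial, club, ciliated, leukocyte, ribosomal protein and oxidative phosphorylation lists had response differences of 0.99, 0.42, 0.31, 0.26, 0.07 and 0.05, above the central 95%, the last at -0.05 with the probe set of highest mean. The mesothelial, club and ciliated lists differed between the genotypes mainly when untreated. Their medians for Tlr4-/- minus wild type were -1.51, -0.84 and -0.37 untreated and -0.36, -0.20 and 0.05 at day 4. For Saa3, Serpina3n and Bcl3 most of the difference lay between the untreated arrays (1.68, 1.10 and 1.40 higher in Tlr4-/-), whereas for Cxcl1 it lay between the day 4 arrays (-0.01 untreated and -1.02 at day 4).

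**Figure D3:**
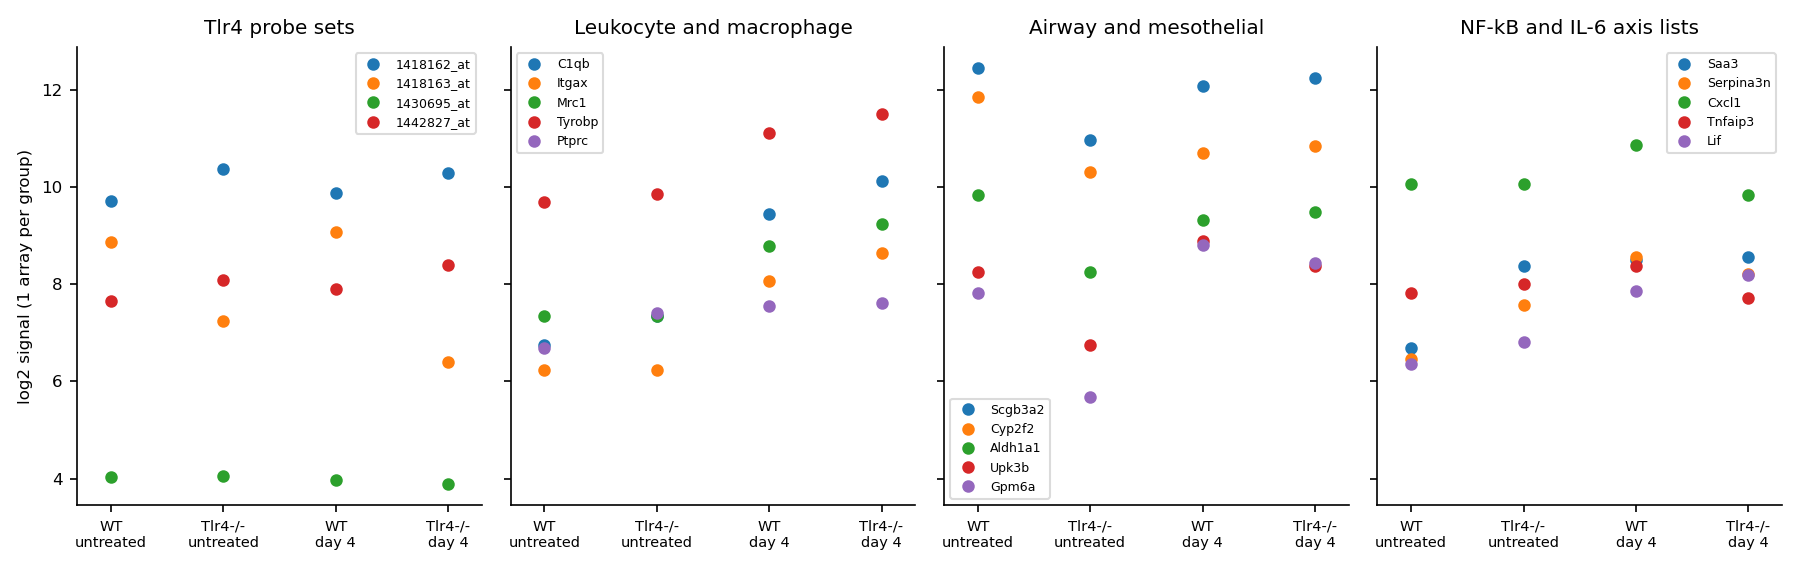
Log2 signal on each of the 4 arrays for the Tlr4 probe sets and for members of the leukocyte, airway, mesothelial, NF-kB and IL-6 lists; each point is 1 array and no error could be drawn. The airway and mesothelial genes are lowest on the Tlr4-/- untreated array, with Gpm6a at 5.67 there and 7.82 on the wild-type untreated array.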

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

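All tests of this part were chosen after the results were seen. For 25 genes the bleomycin difference went opposite ways in the genotypes by more than the spread between arrays, 12 of them among the highest and lowest genes and 13 other members of the lists. The difference was not tested with 1 array per group. The spread is a single standard deviation of 0.23, and how many genes would pass it by noise alone was not estimated. It was itself estimated from differences between the genotypes' responses, so it is no independent yardstick for them. Of the 12, all but Clec4d were picked by the size of their response difference, so opposite directions follow in part from that choice. The response in Tlr4-/- minus that in wild type was 2.67 for Acaa1b, 2.10 for Eda2r, 1.77 for Aldh1a1, 1.69 for Cyp2f2, 1.66 for Scgb3a2, 1.65 for Gatd3a, 1.59 for Tmem198b and 0.56 for Clec4d. It was -1.58 for Slc25a47, -1.57 for Lrrc51, -1.48 for Akr1c19 and -1.39 for Dnajb14. Among the other list members it was 1.44 for Scgb3a1, 0.91 for Cfap126, 0.90 for Col4a3, 0.55 for Rsph1 and 0.52 for Sesn1, and -1.25 for Mcm2, -0.97 for Bcl3, -0.92 for Cebpd, -0.90 for Tgfb3, -0.84 for Tnfaip3, -0.54 for Osmr, -0.53 for Spry2 and -0.53 for Nfkbia. Of 2418 probe sets above the floor with no gene symbol, which no comparison of the report used, 18 were at least 2-fold higher after bleomycin in both genotypes and 9 at least 2-fold lower, against 1.07 and 1.98 for independent lists and 0 of 64 array control probe sets.

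Leukocyte and macrophage genes were higher after bleomycin in both genotypes, 14 of 15 list members. The leukocyte median exceeded the club median by 1.51 in wild type and by 1.37 in Tlr4-/- (95% bootstrap interval over genes 0.36 to 1.99). The mesothelial median was 0.98 in wild type and 1.86 in Tlr4-/-, where it exceeded the leukocyte median of 1.64. Markers of other cells thus did not all rise alike, as a lower share of AEC2 with no other change would make them. A lower share made up by particular other cells was not excluded, and the interval over genes measures no spread between pools. Leukocytes or their RNA among the sorted cells and transcription of these genes in AEC2 cannot be told apart, because both would raise the list. Ptprc, the gene of a surface protein of leukocytes, was higher and passed limma when adjusted over the list alone, but not over all genes. The sort gate was not given in the sources used here.

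More genes were at 2-fold between the genotypes in the untreated pools (102) than at day 4 (9). A scaling difference that depends on brightness is argued against, since cyclic loess left 92 genes untreated and 10 at day 4. For the 31 lower genes, more airway and mesothelial cells in the wild-type pool may account for part: all 3 lists of club, ciliated and mesothelial markers lay below the 2.5th percentile of random lists, yet only 7 of the 31 genes belong to them. For the 71 higher genes, a share of AEC2 large enough to raise them 2-fold in the Tlr4-/- pool would raise AEC2 markers as much. The 9 AEC2 markers with a mean signal under 12, away from saturation, had a median of -0.0725 (95% interval over genes -0.36 to 0.06). Their highest value was 0.17. In cells sorted for AEC2 the share can hardly rise 2-fold, so this outcome was nearly given beforehand. It decides nothing about the 71 genes. A smaller shift in share was not excluded, and the interval measures no spread between pools. A single deviating pool and an effect of genotype were not tested against each other, since each group had 1 array.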

How the results depend on the processing

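The p threshold of 0.01 and the centring of each difference on its median were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the groups share fewer than 2 replicate numbers; the additive limma model compared the treatments within genotype instead. Both correlations across genes stayed within 0.1 of their values under all 6 alternatives run for them. With a 3-fold threshold, the genes higher and lower were 59 and 5 for bleomycin in wild type, 61 and 5 in Tlr4-/-, 3 and 4 between untreated genotypes, 0 and 1 between day 4 genotypes and 12 and 2 for the response difference. With no filter, 81 were lower in wild type after bleomycin, 342 higher and 141 lower in Tlr4-/-, 133 and 84 between untreated genotypes, 18 and 9 at day 4 and 158 and 147 for the response, from about as many dim genes again. With the filter at the 75th percentile, which tests fewer genes, these were 99 and 11, 94 and 43, 30 and 12, 1 higher at day 4, and 20 and 26. With the probe set of highest mean, 127 were lower in Tlr4-/- after bleomycin, 122 higher between untreated genotypes, 11 higher at day 4 and 138 had a response difference of -1 or less; the cause was not tested. Quantile normalization gave 47 lower in wild type after bleomycin and centring of each difference 43, where it also gave 43 higher between untreated genotypes; the cause was not tested. The limma bleomycin calls, higher and lower, were 378 and 106 after centring on array medians, 319 and 48 without the filter, 279 and 62 with the probe set of highest mean, 254 and 61 with no other factor and 306 and 69 at an adjusted p under 0.01; beyond the stricter threshold the cause was not tested. Of the 883 calls, 865 were shared with trend and robust on, 715 with quantile normalization, 617 with cyclic loess, 484 with centring on array medians, 443 with the filter at the 75th percentile, 315 with no other factor, 295 with the probe set of highest mean and 252 without the filter. Leaving out the wild-type untreated, Tlr4-/- untreated, wild-type day 4 or Tlr4-/- day 4 array shared 440, 678, 21 and 0. Leaving out each array in turn, in fits of 2 against 1 whose lone array is assumed to vary like the others, the limma genes higher ranged from 0 to 802 and lower from 0 to 227. The genotype effect had 14 limma calls higher and 4 lower with the filter at the 75th percentile and 0 and 0 under every other alternative run. With the probe set of highest mean the median of Wnt and FGF genes between day 4 genotypes turned to 0.0758, of TGF-beta targets after bleomycin in Tlr4-/- to -0.0066 and of the response of oxidative phosphorylation to -0.0492; the cause was not tested. Of 570 values of named genes under alternatives, 558 moved by less than the spread between arrays and 12 by more; of 175 limma values, which did not include leaving out an array, 173 kept their call, while Gem lost it without the filter and Arntl with the probe set of highest mean. Signal over background could not be judged without detection calls, and genes below the floor were outside every main comparison.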

Other observations

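All tests of this part were chosen after the results were seen. Among circadian clock genes beyond Arntl and Npas2, a set gathered after the values were seen, 2 rose and none fell by limma. Per2, a repressor of the clock, rose by 0.92 ± 0.17 and Tef by 0.70 ± 0.17 (limma average ± SE), while Per3 was higher by 0.54, Per1 by 0.48 and Clock lower by -0.42 without passing. Dbp was higher after bleomycin by 1.32 in wild type and 0.13 in Tlr4-/-, and Nr1d1 differed by -0.60 and 0.02. Beside Il6, the hyaluronan-binding gene Tnfaip6, also below the filter, was higher after bleomycin by 1.06 in wild type and 0.96 in Tlr4-/-.

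Of the 50 genes past the filter nearest to Tlr4 in RefSeq order, 25 on each side, 0 were at 2-fold between the genotypes in either treatment. Over all 9097 genes, 102 were at 2-fold untreated and 9 at day 4. A count of 0 among 50 is near that share and decides nothing. Among the 50, the largest difference in the same direction in both treatments was at least 0.38, for Trim32.

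Y-linked genes were higher and Xist lower after bleomycin in both genotypes. Eif2s3y was higher by 2.04 in wild type and 2.01 in Tlr4-/-, Kdm5d by 1.02 and 1.27 and Uty, a dim gene, by 0.75 and 0.91, while Xist differed by -0.62 and -1.27. A change in Xist expression alone, in pools of the same sexes, would leave the Y-linked increase unaccounted for. The median of that increase, over genes of the smaller genotype value, was 1.02, but it is part of the pattern and no separate test. More male mice in the bleomycin pools stays open as a hypothesis. The increase of 3 of 3 Y-linked genes is the pattern itself and tests nothing further. If the hypothesis holds, sex differs along with bleomycin in both genotypes. The limma bleomycin calls and the genes shared by both genotypes cannot tell the 2 apart. The sex of the mice was not given in the sources used here.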
